A study of Homo sapiens with 6 samples.

How the data were processed

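Chromatin immunoprecipitation of FLAG-tagged GSX2 was analysed from 3 replicates of 1 group of H9-derived cells. Per the labels' protocols, cells were grown in Essential 8 Flex medium and differentiated in Essential 6 medium with inhibitors of BMP, TGF-beta and Wnt signalling, and then with a Wnt secretion inhibitor and Activin A. Per the labels, they were fixed with formaldehyde, chromatin was sheared by sonication, and the amplified libraries were size-selected for short fragments. Peak names in the deposited lists mark the replicates as biological. The labels number them and do not say whether each is a separate culture, so the spread between them may be partly technical. The 3 input libraries have no values here and entered no analysis.

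Per the submitters' processing notes, the tools included Trim Galore, Bowtie2, SAMtools, MACS3 and deepTools and the build was hg38. Their versions and settings, and whether the input served as the control for peak calling, are not given in the sources used here. The authors deposited 1 narrow-peak list per replicate, so peaks were called in each replicate separately. In the deposited lists the fold enrichment of each peak is a linear ratio over the caller's background, and significance is given as −log10 p and −log10 q. The deposited score is the −log10 q multiplied by 10 and truncated, and was not used. The smallest −log10 q in each list was 3.0, so the authors' threshold was a q-value of 0.001. A region of several summits occupies several lines. The 10326, 7779 and 9503 lines of replicates 1, 2 and 3 were reduced to 9936, 7535 and 9204 intervals, keeping the summit of highest fold enrichment. Of these, 77, 64 and 82 lay on unplaced or alternate contigs and were left out of all comparisons. The lists give no read counts, so depth is unknown, and a weak or missing peak can reflect depth.

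Peaks of the 3 lists were merged where they overlapped by at least 1 bp, and a region was called shared where it held a peak of each replicate. Where a replicate had several peaks in a region, the one of highest fold enrichment was kept, and the region's position was the median of the replicates' summits. Observed sharing was set against 100 placements of each list at random positions of the same chromosomes and, as an addition after seeing the data, 100 placements shifted by 20 to 200 kb. Shares of regions have 95% Wilson intervals, which cover counting error only. Fold enrichment was used to describe and rank peaks, with the mean and SD over 3 replicates for shared regions.

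Genes came from a RefSeq table of assembly GRCh38.p14, the same build as hg38, which gives the 2 ends of each gene. It holds no strand, exons or sequence. The planned design changed for this reason. Distance to a start site became distance to either end of the gene span, promoters became windows of 1 kb around either end, and the nearest gene became the nearest protein-coding span. Sequence motifs, enriched short words, the spacing of paired homeodomain cores, and the relation of motifs to location and strength were planned and not run. No sequence was used.

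Gene lists were fixed before the data were examined. They were 24 lists with 471 entries, of which 470 matched a protein-coding gene, 2 of them through an older symbol; 6 genes stand in more than 1 list. They cover ganglionic eminence progenitors, the GABAergic programme, striatal projection neurons, medial eminence, caudal and dorsal lateral eminence interneurons, pallium, diencephalon with hypothalamus and eye, midbrain to spinal cord, HOX genes, neural progenitors, the Notch, Hedgehog and Wnt pathways, FGF, BMP and retinoid signalling, cell cycle, neuronal differentiation, axon guidance, glia, pluripotency, mesoderm with endoderm and neural crest, liver, skeletal muscle, blood and ribosomal proteins. The members nearest to at least 1 shared region were counted and compared with 10000 random lists of the same size, drawn from the same 20 bins of territory length, a permutation of genes within bins. The two-sided p is 2 times the smaller tail, at least 0.0002, the smallest these lists can give, with Benjamini-Hochberg adjustment over lists. Members with a region within 1 kb of an end were compared with all 19974 protein-coding genes by Fisher's exact test, two-sided, adjusted in the same way.

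Genes were named by a rule fixed in advance. GSX2, GSX1, DLX1, DLX2, DLX5, DLX6, PAX6, NKX2-1 and GLI3 were named whatever their values, as were the nearest genes of the 10 shared regions of highest mean fold enrichment. In each list, up to 4 members (lists past the test) or 2 (other lists) with the strongest shared region were named, leaving out chromosome Y. Some genes that this rule names are not reported here.

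The steps were tested on simulated data. All 1000 sites planted at nearly the same positions in 3 random lists were recovered as shared, which checks the merging only. For null lists of genes with long territories, among 19974 genes, the matched test gave p under 0.05 in 2% of lists and an unmatched test in 44%. Lists of 20 such long-territory genes hit at 3 times the chance rate were recovered in 100% of trials, at an unadjusted p under 0.05. Power was not measured for smaller ratios, for short territories or after adjustment over lists. Alternatives covered overlap rules, stricter thresholds, lists of equal length, windows of 2.5 kb and 500 bp, protein-coding genes only, a limit of 100 kb, no matching, 100 territory bins, and leaving out each replicate. With a replicate left out, a shared region needed a peak of both remaining replicates. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.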

Results

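GSX2 is a homeodomain transcription factor of progenitors in the lateral ganglionic eminence, the embryonic forebrain region that gives rise to striatal neurons and olfactory interneurons. Its genome-wide binding was measured by chromatin immunoprecipitation and sequencing in H9 cells, an established human embryonic stem cell line, steered toward lateral ganglionic eminence-like progenitors. The cells carried a doxycycline-inducible transgene for wild-type GSX2 with a tandem FLAG tag. Doxycycline at 100 ng/mL was given for 12 hours from day 10, and chromatin taken at day 10.5 was precipitated with the M2 antibody against FLAG. The series title names repression by GSX2 in the developing basal ganglia, and the question these data address is which regions and genes the tagged protein occupied. The values used here are 3 peak lists, 1 for each ChIP replicate. The 3 input libraries have no values here, and no precipitation from cells without the transgene was analysed. There is therefore 1 group and no contrast between conditions. The peak lists hold no read counts, so the sequencing depth of each replicate is unknown.

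The GSX2 peaks as called were narrow, and the strongest of them recurred in all 3 replicates. The lists held 9859, 7471 and 9122 peaks on chromosomes 1 to 22 and X in replicates 1, 2 and 3, a mean of 8817 ± 1223 (SD, n = 3). Median peak width was 279, 223 and 222.5 bp, and the smallest was 193, 159 and 157 bp. Widths depend on the caller's settings, which are not known here. Median fold enrichment, the authors' own value for each peak, was 7.15, 7.73 and 7.48, a mean of 7.45 ± 0.29 (SD, n = 3). Merging overlapping peaks gave 15743 regions, of which 3537 held a peak of every replicate (22.5%, 95% Wilson interval 21.8 to 23.1%). Another 3568 regions were seen in 2 replicates and 8638 in 1. Median fold enrichment was 9.49 in regions of all 3 replicates, 7.18 in regions of 2 and 6.21 in regions of 1.

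Among the strongest 10% of a replicate's regions by q-value, 94.0% ± 2.1 (SD, n = 3) were found in all 3 replicates, against 12.4% ± 5.7 of the weakest 10%. Random placement of the same peaks on their chromosomes gave at most 1 region common to all 3 lists in any of 100 placements. Over the shared regions, fold enrichment correlated between replicates with Spearman coefficients of 0.582, 0.596 and 0.601 and Pearson coefficients of 0.644, 0.655 and 0.661 on the log2 scale. These correlations run across regions, which are not independent replicates. The median coefficient of variation of fold enrichment between replicates was 19.5%. A minimum −log10 q of 10 left 1904 shared regions.

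**Figure D1:**
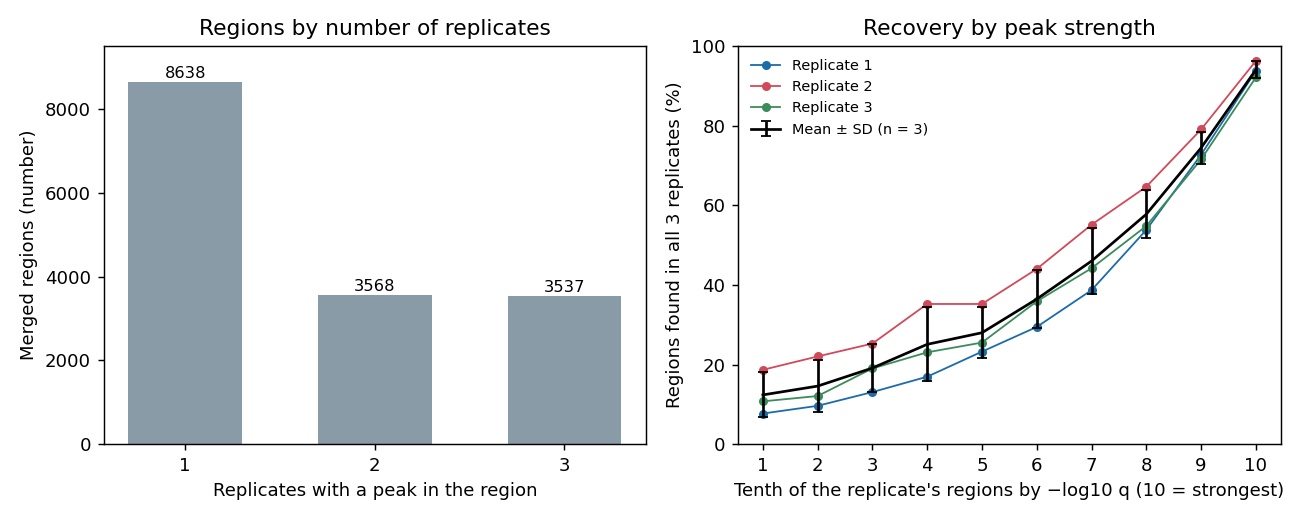
Left, number of merged regions (vertical axis) by the number of replicates with a peak in them. Right, percentage of each replicate's regions found in all 3 replicates (vertical axis) in 10 equal groups of the regions ranked by −log10 q (horizontal axis), with coloured lines for replicates and black for their mean ± SD, rising from 12.4% in the weakest group to 94.0% in the strongest.

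Of the 10 strongest shared regions, 5 lay inside a protein-coding gene and 5 outside. The first by mean fold enrichment was inside ADGRL3, a latrophilin-type adhesion receptor (chromosome 4, 61506202 to 61506833, 44.3 ± 8.5-fold, SD, n = 3 here and for the regions that follow). Next were regions inside PTPRG, a receptor tyrosine phosphatase (chromosome 3, 61682503 to 61683236, 43.5 ± 10.5-fold), and inside THADA (chromosome 2, 43484273 to 43484935, 42.3 ± 4.0-fold). A region inside PIK3C2G, a lipid kinase gene, reached 38.4 ± 7.1-fold (chromosome 12, 18369109 to 18370281). A region 31.6 kb from WNT9A, which encodes a Wnt ligand, reached 37.3 ± 2.7-fold (chromosome 1, 227886709 to 227887323). A region 104.4 kb from RASGRP1, a Ras exchange factor gene, reached 36.9 ± 2.5-fold (chromosome 15, 38668875 to 38669558). TLE4, a Groucho-type corepressor gene, held a region of 36.7 ± 4.3-fold inside its span (chromosome 9, 79660237 to 79660945). The last 3 were 141.0 kb from KDM4C, a histone demethylase gene (35.9 ± 4.5-fold), 34.5 kb from MRPL36 (34.9 ± 6.8-fold) and 2.59 kb from EXOSC2 (34.7 ± 4.3-fold). With SDs of this size, the order within these 10 regions is not resolved.

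Peaks were more frequent near the ends of genes than random positions were, but most lay elsewhere. Per replicate, 13.7% ± 0.43 (SD, n = 3) of peaks were within 1 kb of either end of an annotated gene, against 6.08% ± 0.03 of randomly placed peaks, a ratio of 2.25 ± 0.07. A further 56.5% ± 0.2 lay inside genes away from the ends (51.7% at random) and 29.8% ± 0.2 between genes (42.2% at random). When random positions were drawn within 20 to 200 kb of each peak, the share inside genes was 57.8%, above the observed share, while the ratio at gene ends remained 2.19. The annotation used here gives the 2 ends of each gene and no strand or exons, so start sites, exons and introns were not separated. With protein-coding genes only, 8.72% of peaks were near an end and the ratio was 3.75 ± 0.15.

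The regions shared by all 3 replicates were less often at gene ends than those of 1 replicate. Of the shared regions, 437 were near a gene end (12.4%, 95% Wilson interval 11.3 to 13.5%), against 1281 of the single-replicate regions (14.8%, 14.1 to 15.6%; odds ratio 0.81, two-sided Fisher's exact test, p = 0.000337). Among shared regions, 10.2% of the strongest 25% by fold enrichment and 16.2% of the weakest 25% were near a gene end (odds ratio 0.588, two-sided Fisher's exact test, p = 0.000244). Both p-values were 0.000337 after Benjamini-Hochberg adjustment over the 2 comparisons. Both comparisons were chosen after seeing the data. Regions are their units, so they describe these libraries.

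**Figure D2:**
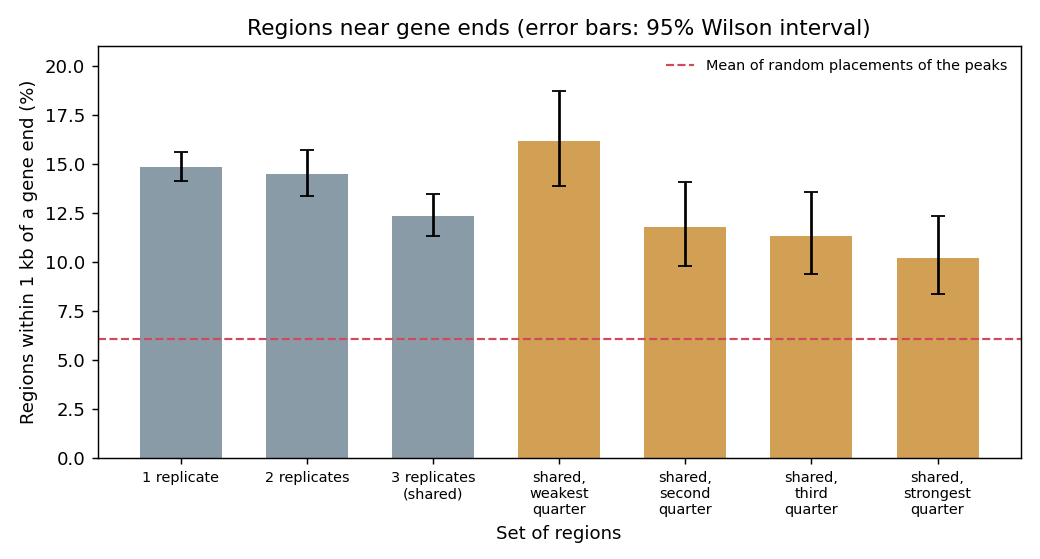
Percentage of regions within 1 kb of either end of an annotated gene (vertical axis) for regions of 1, 2 or 3 replicates (grey) and for shared regions in 4 equal groups by mean fold enrichment (ochre), with 95% Wilson intervals as error bars. The dashed line is the mean of randomly placed peaks, 6.08%; the shares fall from 16.2% in the weakest of these groups to 10.2% in the strongest.

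Shared regions fell at genes of 7 lists more often than at matched genes: ganglionic eminence progenitors, pallium, midbrain to spinal cord, neural progenitors, the Notch pathway, FGF, BMP and retinoid signalling, and axon guidance. Each region was assigned to the nearest protein-coding gene, which gave 2450 genes (12.3% of 19974) at least 1 shared region. Of 24 gene lists, 7 had more members with a region than 10000 random lists matched on territory, the stretch over which a gene is the nearest (two-sided permutation test of genes within territory bins, Benjamini-Hochberg adjusted p under 0.05). None had fewer, and 0 lists had fewer at an unadjusted p under 0.05. For lists with few expected members a deficit could not be called even with 0 members hit. Blood and immune genes, with 0 of 20 against 1.58 expected, had an unadjusted permutation p of 0.290. The random lists were matched on territory alone. No measure of open chromatin in these cells entered, so its part in the excess was not tested. With only peaks of −log10 q of at least 10, the list of FGF, BMP and retinoid signalling alone passed (adjusted permutation p = 0.0432). The other 6 lists then had ratios of observed to expected members of 1.80 to 2.64, against 1.56 to 2.61 with all peaks, on fewer regions. Without replicate 2, 3 lists passed, those of the ganglionic eminence, of midbrain, hindbrain and spinal cord, and of axon guidance. A shared region then needed a peak of replicates 1 and 3 only, which gave 5185 regions and raised the expected members. The pallial list kept 11 members against 6.33 expected, and the Notch list 11 against 6.63. FGF, BMP and retinoid signalling kept 13 against 7.41, and neural progenitors had 13 against 8.65. None of these lists lost a member.

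**Figure D3:**
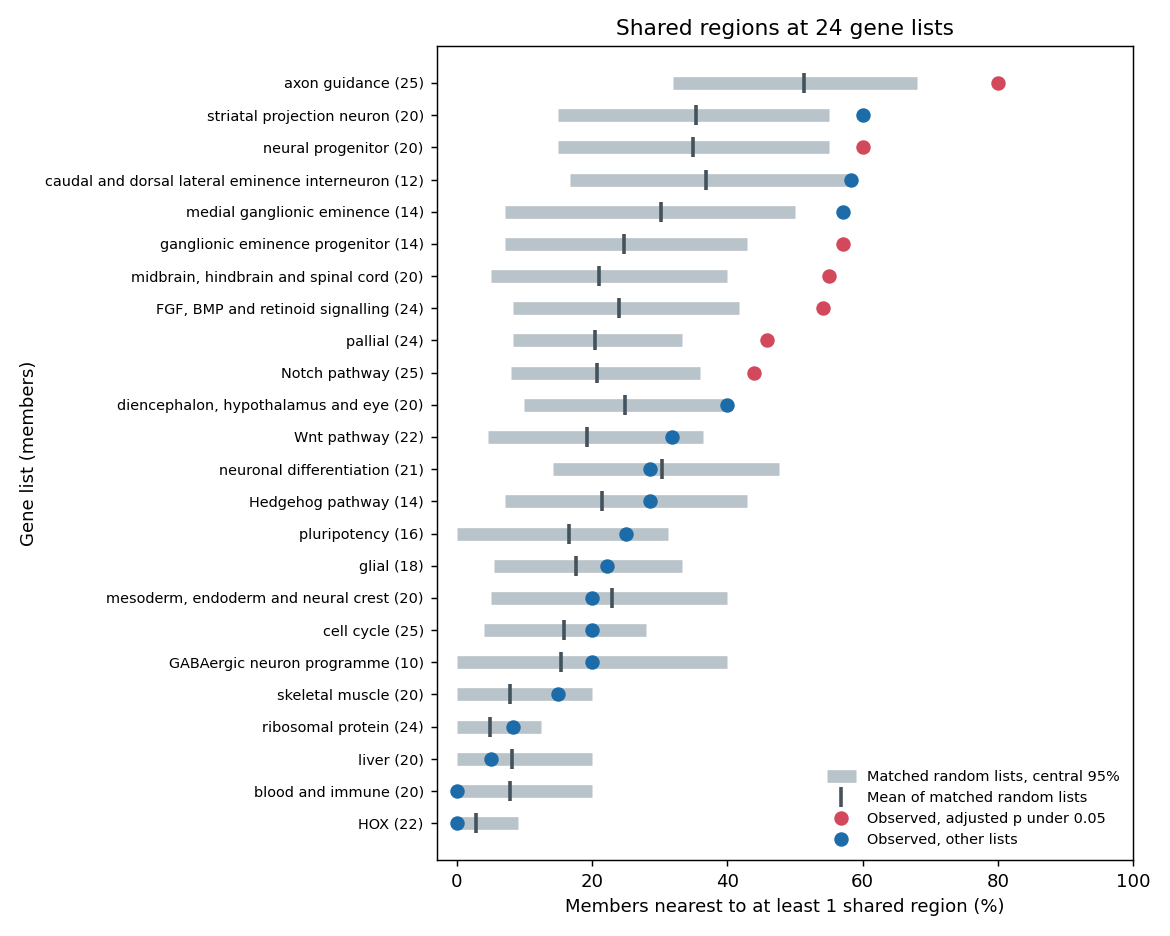
Percentage of each list's members nearest to at least 1 shared region (horizontal axis) for 24 gene lists (vertical axis, number of members in parentheses). Points are observed values, red where the adjusted p was under 0.05; bars span the central 95% of random lists matched on territory and ticks mark their mean, as for axon guidance with 80.0% observed.

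The ganglionic eminence progenitor list had 8 of 14 members with a shared region, against 3.46 expected (adjusted permutation p = 0.0224). Its strongest regions were inside GSX2 itself (32.5 ± 16.0-fold), inside MEIS1, a TALE homeodomain gene (16.0 ± 4.5-fold), and 6.83 kb from SP8, a zinc finger gene of the dorsal eminence (14.5 ± 2.4-fold). Without GSX2, whose coding sequence the transgene also carries, 7 of 13 members had a region and the adjusted permutation p was 0.0763. Without replicate 3 it was 0.0533. The striatal projection neuron list had 12 of 20 members with a region against 7.07 expected and did not pass (adjusted permutation p = 0.0702), though it did without replicate 3 (adjusted permutation p = 0.0108), with regions of at least 2 replicates (0.0192) and with regions within 100 kb (0.0487). Its strongest regions were 57.5 kb from the dopamine receptor gene DRD2 (22.1 ± 3.6-fold) and inside the retinoic acid receptor gene RARB (17.3 ± 6.9-fold).

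Lists of neighbouring ventral territories did not pass in the planned main test, and some did under alternatives. The medial ganglionic eminence list had 8 of 14 members with a region against 4.23 expected (adjusted permutation p = 0.0709, 0.0312 without replicate 1 and 0.0331 with regions of at least 2 replicates). Its strongest were a region 73.6 kb from NKX2-1, the determinant of that eminence (27.5 ± 2.5-fold), and one 1163 kb from ZEB2 (18.4 ± 2.4-fold). The list of caudal and dorsal lateral eminence interneurons had 7 of 12 against 4.43 expected (adjusted permutation p = 0.328). Counted by regions over its members it passed, with 25 regions against 8.42 expected (adjusted permutation p = 0.024). It was led by the nuclear receptor genes NR2F1 (27.9 ± 6.8-fold, 336.8 kb away) and NR2F2 (21.4 ± 4.0-fold, 483.1 kb away), which had 5 and 8 shared regions. The GABAergic neuron programme had 2 of 10 against 1.54 expected (adjusted permutation p = 1), at SP9 (9.11 ± 1.33-fold, 4.50 kb away) and inside GAD2, a GABA-synthesising enzyme gene (7.63 ± 1.07-fold).

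Genes of the pallium, the dorsal telencephalon that gives rise to excitatory cortical neurons, passed with 11 of 24 members against 4.89 expected (adjusted permutation p = 0.0144). They included TFAP2D (19.8 ± 4.8-fold, inside the gene), the proneural gene NEUROG2 (18.8 ± 1.3-fold, 7.48 kb away), the dorsal progenitor regulator PAX6 (18.8 ± 6.1-fold, inside the gene) and DMRTA1 (13.0 ± 0.7-fold, 207.4 kb away). Without replicate 2 the adjusted permutation p was 0.0987. The list of midbrain, hindbrain and spinal cord genes had the highest ratio among the 7, with 11 of 20 members against 4.21 expected (adjusted permutation p = 0.0096). It included PAX3 (19.5 ± 1.0-fold, 23.1 kb away), EVX1 (14.6 ± 2.5-fold, 3.32 kb away), NKX6-1 (14.0 ± 1.9-fold, 84.1 kb away) and LMX1B (13.7 ± 1.1-fold, inside the gene), transcription factor genes of caudal neural tube domains. The 11 also count GATA4 (11.1 ± 3.2-fold, 34.3 kb away), which the list of mesoderm, endoderm and neural crest holds as well. GATA4 was named after its value was seen. The list of diencephalon, hypothalamus and eye had 8 of 20 against 4.98 expected (adjusted permutation p = 0.328), led by TCF7L2 (27.9 ± 7.7-fold, inside the gene) and IRX3 (12.9 ± 3.3-fold, 3.32 kb away). It passed without replicate 1 (adjusted permutation p = 0.0267) and without replicate 3 (adjusted permutation p = 0.0336), with regions of at least 2 replicates (0.0315) and by number of regions (0.0341). None of the 22 HOX genes tested was nearest to a shared region, with 0.612 expected.

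Neural progenitor genes had 12 of 20 members with a region against 6.97 expected, close to the threshold (adjusted permutation p = 0.0494). SOX2, a core factor of neural stem cells, had 8 shared regions, the strongest 3.75 kb away (29.0 ± 5.3-fold). POU3F2 (24.5 ± 1.7-fold, 109.9 kb away), SOX11 (14.4 ± 4.4-fold, inside the gene) and SOX1 (13.7 ± 1.5-fold, 93.2 kb away) followed. The adjusted permutation p was 0.117 without replicate 2, 0.0528 without replicate 3 and 0.0542 with 100 territory bins. It was 0.0576 when GSX2 was left out of its own list, through the adjustment alone, since the counts here did not change.

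Among signalling lists, Notch pathway genes had 11 of 25 members with a region against 5.17 expected (adjusted permutation p = 0.0224, and 0.117 without replicate 2). The corepressor genes TLE4 (9 shared regions) and TLE1 (15.3 ± 4.3-fold, inside the gene) and the ligand genes JAG1 (16.0 ± 2.7-fold, 34.5 kb away) and DLL1 (14.7 ± 2.0-fold, 46.7 kb away) had its strongest regions. The list of FGF, BMP and retinoid signalling had 13 of 24 against 5.76 expected (adjusted permutation p = 0.0120, 0.0696 without replicate 2 and 0.0986 by number of regions). It was led by BMP7, a secreted ligand (28.1 ± 3.5-fold, 243.7 kb away), the ETS factor gene ETV5 (22.5 ± 5.9-fold, inside the gene), the receptor gene FGFR1 (19.9 ± 0.9-fold, inside the gene) and SPRY2, a feedback inhibitor of FGF signalling (18.5 ± 0.8-fold, 20.5 kb away). Hedgehog pathway genes had 4 of 14 against 3.01 expected (adjusted permutation p = 0.934), with the strongest regions in GLI3 and CDON (9.49 ± 0.34-fold). Counted by regions over its members this list passed, with 15 regions, 11 of them at GLI3, against 4.5 expected (adjusted permutation p = 0.0254). Wnt pathway genes had 7 of 22 against 4.23 expected (adjusted permutation p = 0.396), with the strongest at FZD8 (17.6 ± 4.5-fold, 1.02 kb away) and inside TCF7L1 (14.6 ± 4.4-fold).

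Axon guidance genes had 20 of 25 members with a region against 12.8 expected (adjusted permutation p = 0.0144). Their territories are long, a median of 948 kb, so chance alone gives many of them a region. SEMA5A, a semaphorin gene, held the strongest (29.4 ± 3.0-fold, inside the gene), followed by regions nearest to the Eph receptor gene EPHA7 (16.2 ± 2.4-fold, 646.8 kb away), the netrin receptor gene UNC5D (13.7 ± 2.7-fold, 560.3 kb away) and EPHA3 (13.3 ± 3.7-fold, 494.2 kb away). Counting only regions within 100 kb, 16 of 25 had one and the adjusted permutation p was 0.149.

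Lists of differentiated and unrelated cells did not depart from matched random lists at this threshold. Neuronal differentiation genes had 6 of 21 members with a region against 6.37 expected, at MAP2 (14.7 ± 1.0-fold, inside the gene) among others. Glial genes had 4 of 18 against 3.17 (NFIX, 10.6 ± 2.7-fold, inside the gene, and SOX8, 8.70 ± 2.27-fold at 32.6 kb). Cell cycle genes had 5 of 25 against 3.96 (MKI67, 12.1 ± 3.3-fold at 570.6 kb, and CDKN2C, 11.3 ± 1.9-fold at 4.76 kb). Pluripotency genes had 4 of 16 against 2.66, nearest to ZFP42 (13.5 ± 0.3-fold at 27.1 kb) and SALL4 (12.3 ± 2.2-fold at 108.1 kb) among others. Genes of mesoderm, endoderm and neural crest had 4 of 20 against 4.60, including FOXD3 (21.4 ± 1.8-fold at 122.6 kb) and MSX2 (19.7 ± 9.4-fold at 3.44 kb). Liver genes had 1 of 20 against 1.63 (APOB, 14.8 ± 5.1-fold at 75.9 kb). Skeletal muscle genes had 3 of 20 against 1.58 (CASQ1, 14.9 ± 3.2-fold, and NEB, 7.98 ± 0.53-fold, both inside the gene). Ribosomal protein genes had 2 of 24 against 1.18, both from distant regions (RPS24, 8.33 ± 2.75-fold at 416.1 kb, and RPLP1, 6.63 ± 2.20-fold at 279.0 kb). The muscle and ribosomal ratios, 1.90 and 1.69, were within the range of the called lists, 1.56 to 2.61, on few expected members. Blood and immune genes had 0 of 20 against 1.58 expected (adjusted permutation p = 0.535). Over these 9 lists the adjusted p ranged from 0.535 to 1.

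Fewer lists passed when only regions close to the ends of genes were counted. Shared regions lay within 1 kb of an end of 310 protein-coding genes (1.55%). Each list was therefore expected to have only 0.155 to 0.388 such members, and the smaller number of calls does not show weaker enrichment. The Notch ratio, for example, was 7.73 here and 2.13 for nearest regions. Of the 24 lists, that of ganglionic eminence progenitors passed, with GSX2, MEIS1, SIX3 and SP8, 4 of 14 members, against 0.217 expected (two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.00121). Without GSX2, 3 of 13 members remained and the adjusted p was 0.0226. HES5, JAG1 and TLE4 of the Notch pathway had such a region (3 of 25, Fisher's exact p = 0.00661, adjusted p = 0.0793). Within 2.5 kb, the Notch list (4 of 25) and the pallial list (4 of 24) also passed (Fisher's exact test, adjusted p = 0.0352 for both). Without replicate 3, 4 of 24 genes of FGF, BMP and retinoid signalling had one and that list passed as well (Fisher's exact test, adjusted p = 0.0154). SIX3 and HES5 were named after their values were seen.

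At the GSX2 locus (chromosome 4, gene span 54100163 to 54102498), 3 shared regions were nearest to the gene. The strongest, inside the gene at 54101581 to 54101918, had fold enrichments of 21.5, 50.9 and 25.2 in replicates 1, 2 and 3. Another inside the gene, at 54100348 to 54100919, had 13.3, 15.5 and 20.2. The last lay outside it, at 54098407 to 54098755, with 10.7, 14.0 and 12.2. Peaks inside the gene cannot be assigned to the chromosomal copy or to the transgene from these values. One more shared region, 84.5 kb from the gene and nearest to CHIC2, had a mean of 15.2 ± 3.2-fold.

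GLI3, which encodes a transcriptional effector of Hedgehog signalling with a strong repressor form, had 11 shared regions, 9 of them inside its span (chromosome 7, 41960949 to 42264268). Its territory of 754 kb would hold 0.880 at the genome-wide density, a ratio of 12.5. The strongest, at 42052587 to 42052996, reached 18.5 ± 6.3-fold. PAX6 (chromosome 11, 31789026 to 31817961) had 2 shared regions inside its span, at 31799309 to 31799803 (18.8 ± 6.1-fold) and 31815474 to 31815871 (10.7 ± 0.7-fold), and a further one 58.2 kb away (9.20 ± 3.29-fold). Another shared region, 25.4 kb from PAX6 and nearest to ELP4, had 5.92 ± 1.87-fold. NKX2-1 had 1, at 36442408 to 36443706 on chromosome 14. GSX1, the closest relative of GSX2, had 1 weak shared region 47.5 kb away (7.64 ± 2.25-fold).

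DLX1, DLX2, DLX5 and DLX6, regulators of ganglionic eminence neurogenesis, had no region shared by all 3 replicates within 100 kb. DLX1 and DLX2 had 1 peak in this range, of 5.30-fold in replicate 1, and DLX5 and DLX6 had 2, of 4.95-fold in replicate 2 and 4.20-fold in replicate 1. These values are below the median fold enrichment of their replicate's list.

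**Figure D4:**
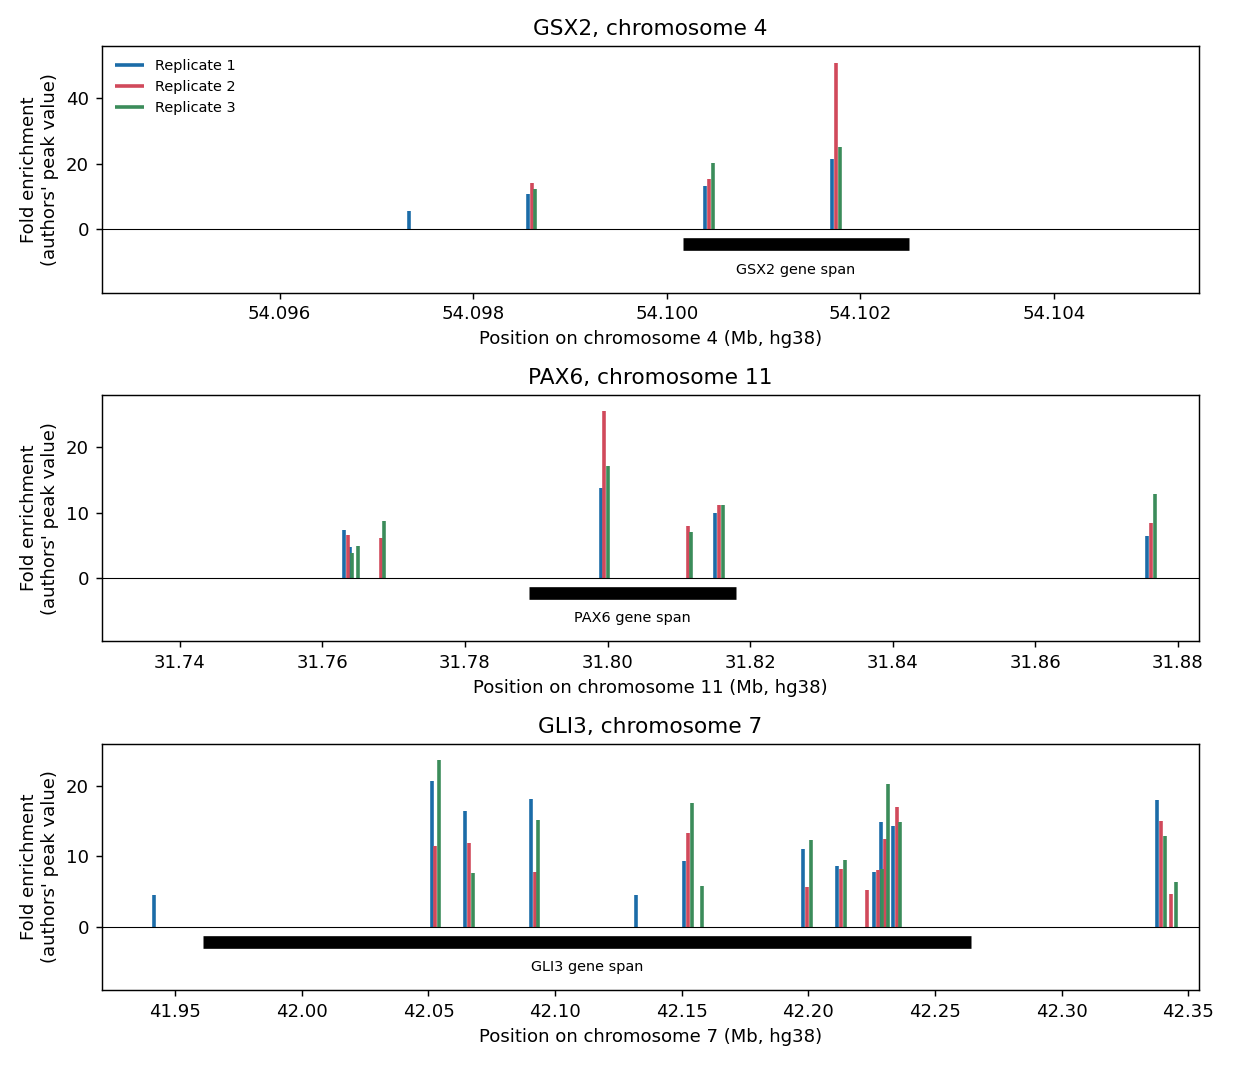
Fold enrichment of every peak (vertical axis, the authors' value for each peak) by position on the chromosome (horizontal axis, Mb, hg38) around GSX2, PAX6 and GLI3, with 1 colour per replicate, replicates drawn side by side with a small offset, and the gene span as a black bar. The strongest GSX2 peak ranges from 21.5 to 50.9-fold between replicates, and GLI3 holds 9 regions with peaks of all 3 replicates inside its span.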

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

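The tests of the GSX2 gene, of single-replicate regions and of the contigs in this part were chosen after the values they measure were seen, except the gene list test of single-replicate regions.

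Peaks outside the chromosomes used in the comparisons clustered on contigs KI270733v1 and GL000220v1, which carry ribosomal RNA gene repeats. KI270733v1 held 10, 16 and 16 peaks in replicates 1, 2 and 3, and GL000220v1 held 8, 8 and 12, each above the 3 that a count of 0 allows. These were wide stretches of low enrichment, with median folds of 3.31, 3.51 and 3.01 over both contigs. High local background of repeated sequence is a candidate explanation. It predicts a low fold for a given significance, and the median peak there had a lower fold than nearly every chromosome peak of similar −log10 q, at a percentile of 0.0512 in replicate 2 and 0 in the others. No biological explanation was tested, since input values were not used here.

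The strong peaks inside the GSX2 gene may come from transgene DNA, which carries the coding sequence. If the input served as the control for peak calling, which is not known, extra copies would raise signal and background together. That would give a high −log10 q for the fold. Among peaks of similar fold, the peak at 54101581 was at the 99.2, 50 and 100 percentile of −log10 q in replicates 1, 2 and 3, and that at 54100348 at the 99.6, 95.1 and 72.0 percentile. In replicate 2 only 2 peaks were strong enough to compare with the first. These values do not decide the matter, so transgene DNA and binding to the chromosomal gene cannot be told apart inside the gene. The peak outside it, at 54098407, was at the 71.7, 62.4 and 86.2 percentile. With the control unknown, these values do not decide whether extra copies contribute there.

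Of the 15743 merged regions, 8638 were seen in 1 replicate. The peak-calling threshold is a candidate explanation, and sharing rose with strength to 94.0% in the strongest 10% of a replicate's regions. Weak noise peaks would give such a rise too, so it does not tell a threshold effect from noise. Noise placed evenly along the chromosomes is argued against as the whole cause, by location only. These regions lay near gene ends in 14.8% of cases (Wilson lower bound 14.1%), against at most 6.47% in 20 random placements. They raised 0 of the 7 gene lists called for shared regions, with ratios of 1.06 to 1.55 and adjusted permutation p of at least 0.216. The prediction written beforehand for noise was at most 1 list, and it was met. Noise that itself favours gene ends therefore stays open. This test is limited, since many members were expected by chance, 18.8 of 25 for axon guidance. Before adjustment, the permutation p was 0.018 for the Notch list (14 against 9.05 expected). For FGF, BMP and retinoid signalling it was 0.0412 (15 against 10.2).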

How the results depend on the processing

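The null of shifted peaks, the 100 bins, the leaving out of GSX2, the matched test at gene ends and the 2 comparisons of region classes at gene ends, with their alternatives, were chosen after seeing the data. No paired analysis was possible because the input libraries that share the replicate numbers have no values here. Alternatives for motifs, short words, core spacing, motif and location, and motif and strength were not run, as no sequence was used. Depth is not recorded in the lists, so its effect was not tested.

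With 1 replicate left out, the number of shared regions was 4430 to 5185. A region then needed a peak in 2 replicates instead of 3, so a higher number follows from the looser rule. The number stayed within 1.5 times of 3537 under other overlap rules, equal lists and −log10 q of at least 5. It fell to 1904 at −log10 q of at least 10, which keeps fewer peaks. The mean Spearman coefficient of 0.593 was 0.667 for −log10 q; the cause was not tested. The share near gene ends was 23.1% within 2.5 kb, 8.84% within 500 bp and 8.72% for protein-coding genes, by construction of the window or gene set, and 11.5% at −log10 q of at least 10. It was 13.5 to 13.9% with 1 replicate left out. Both comparisons at gene ends kept their direction and threshold in every alternative run.

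The 7 lists called became 12 with no matching, which ignores territory, and 1 at −log10 q of at least 10, which leaves fewer regions. They were 3 to 9 with 1 replicate left out, where a peak in both remaining replicates was enough and expected members rose. The number called was 10 with regions of at least 2 replicates, 9 by number of regions and 7 within 100 kb. With 100 bins they were 6, and with GSX2 left out 5. Except in the last case, the cause was not tested. Without GSX2, the ganglionic eminence list went from 8 of 14 to 7 of 13 members. The neural progenitor list kept 12 members against 6.97 expected and lost its call through the adjustment alone. Lists called at gene ends went from 1 to 3 within 2.5 kb (Notch and pallial genes added) and 1 to 2 with 1 replicate left out. Of 240 list values under alternatives, 188 kept direction and side of the threshold, 17 lost the call, 16 gained it and 19 changed direction. All 19 belong to lists not called under the main setting or that alternative; the cause was not tested. As ratios to expectation, these were 0.761 (shared by at least 2) and 0.952 (without replicate 2) for the GABAergic programme and 0.938 (−log10 q of at least 10) for diencephalon, hypothalamus and eye. Cell cycle gave 0.962 (at least 2) and 0.82 (number of regions), and pluripotency 0.864 (number of regions). Neuronal differentiation gave 1.06 (within 100 kb), 2.33 (no matching), 1.08 (at least 2) and 1.09 (without replicate 3; below 1 without either other replicate, lowest 0.888). Glia gave 0.993 (at least 2) and 0.492 (−log10 q of at least 10). Mesoderm, endoderm and neural crest gave 1.63 (no matching), 1.36 (−log10 q of at least 10), 1.15 (number of regions) and 1.1 (without replicate 3; below 1 without either other replicate, lowest 0.842). Ribosomal proteins gave 0 (within 100 kb), 0.679 (no matching) and 0 (−log10 q of at least 10).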

Other observations

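Several genes that the naming rule did not reach collected many shared regions; they were chosen after their values were seen. ZNF608, a zinc finger gene, had 14, the highest number of any gene, against 1.67 expected from its territory of 1428 kb. CADPS2 and DACH1, a transcription factor gene, had 9 each, against 0.729 and 1.77 expected. OTX2, a homeodomain gene of forebrain and midbrain, had 7 against 0.320 expected, a ratio of 21.9. EMX2, a homeodomain gene of the pallium, had 6 against 0.372 expected, a ratio of 16.1. ZFHX4 had 8 against 0.934. In all, 48 genes had 5 or more shared regions and 1800 had 1, over a mean density of 1.17 shared regions per Mb.

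Gene families read from symbols, also chosen after seeing the data, gave 1 departure among 25. Solute carrier genes had a region at 24 of 347 members against 40.8 expected in lists matched on territory (adjusted permutation p = 0.025). Olfactory receptor genes had 8 of 390 against 19.1 expected (adjusted permutation p = 0.0525), and GABA receptor genes 1 of 19 against 5.28 (adjusted permutation p = 0.0958). PAX genes had 6 of 9 against 2.07 expected (adjusted permutation p = 0.0837), LIM homeobox genes 6 of 12 against 2.35 (adjusted permutation p = 0.0958) and semaphorin genes 9 of 20 against 4.52 (adjusted permutation p = 0.0837).

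One hypothesis was that shared regions may favour ventral telencephalon genes over those of other neural tube regions. The gene lists to compare were named before any result was seen. The comparison was first run with the GABAergic list added, and on the named lists alone only after that result was known. Of the 60 genes in the named ganglionic eminence, striatal and interneuron lists, 35 had a shared region (58.3%), against 19 of 40 in the lists from diencephalon to spinal cord (47.5%). The difference of 10.8 percentage points lay inside the central 95% of label permutations within 4 groups of territory length, from -14.2 to 19.2 points (two-sided permutation p = 0.482, 10000 permutations). With the GABAergic list added, 37 of 70 genes had a region (52.9%; permutation p = 0.823). Whether the 2 sets differ is left open.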
